A study of Mus musculus with 59 samples.

How the data were processed

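Total RNA of treated and untreated melan-a cells was extracted with a column kit and labelled indirectly with Cy3 and Cy5, per the labels' protocols. On every array channel 2 held the treated RNA, in Cy5 on the arrays of the direct and in Cy3 on those of the reverse orientation. The deposited values are log ratios of the 2 channels, taken as log2: a base of 10 is excluded by sizes of up to 10.258, but base 2 is assumed and not stated. The scanner, the image software, the filter that left spots without a value, and any normalization the authors applied are not given in the sources used here, and no channel intensities were used. The direction is likely treated over untreated, because the design text writes treated/untreated. The values cannot test this reading, because exchanging numerator and denominator on all arrays leaves every correlation between arrays unchanged. The correlations can show only whether ratios were oriented by treatment or by dye. In ratios oriented by dye, the arrays would share their dye bias, which would raise the correlations between opposite dye orientations. In ratios oriented by treatment, the dye bias turns sign with the dye of the treated RNA and lowers them. The median correlation between arrays of opposite dye orientation was -0.242. Over 18694 probes with a value on all arrays, centred ASP 3 d arrays with treated RNA in Cy5 correlated at 0.33 with ASP 4 d arrays with treated RNA in Cy3, and at 0.202 in the opposite choice of dyes. ASP at 2 d and 3 d gave 0.207 and 0.218, but ASP at 1 d and 4 d gave -0.016 and 0.027. For α-MSH at 3 d and 4 d the same correlations were -0.322 and -0.398 in centred values, where dye bias dominates, and 0.146 and 0.129 after the loess correction described below. Between α-MSH at 3 h and 1 d they were -0.815 and -0.758, and -0.467 and -0.29 after loess. Such negative values argue for a dye bias that turned sign, and so for ratios oriented by treatment. The mean profiles of these groups correlated at only 0.061, and 0.026 after loess, so a shared response could hardly raise the correlations of this pair. Between arrays of one dye orientation the lowest correlation was -0.22.

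The values showed a strong dye bias. The median was below 0 on 26 of 29 arrays with treated RNA in Cy5 and above 0 on 29 of 30 with treated RNA in Cy3. This turn of sign also argues for ratios oriented by treatment, whichever the numerator. For α-MSH at 3 h they were -0.546, -0.631 and -0.527 with treated RNA in Cy5 and 0.47, 0.5 and 0.417 with it in Cy3. With α-MSH at 1 d the medians were -0.337, -0.55 and -0.457 with treated RNA in Cy5 and 0.267, 0.505 and 0.371 with it in Cy3. α-MSH at 2 d had medians of -0.255, -0.497 and -0.297 with treated RNA in Cy5 and 0.151, 0.416 and 0.27 with it in Cy3. For α-MSH at 3 d they were -0.22, -0.415 and -0.921 with treated RNA in Cy5 and 0.381, 0.447 and 0.356 with it in Cy3. With α-MSH at 4 d the medians were -0.322, -0.529 and -0.769 with treated RNA in Cy5 and 0.175, 0.271 and 0.577 with it in Cy3. ASP at 3 h had medians of -0.622, -0.807 and -0.24 with treated RNA in Cy5 and 0.69, 0.245 and 0.35 with it in Cy3. For ASP at 1 d they were -1.435, -0.06 and -0.219 with treated RNA in Cy5 and 0.207, 0.19 and 0.371 with it in Cy3. With ASP at 2 d the medians were 0.108 and 0.017 with treated RNA in Cy5 and 0.186, 0.002 and -0.011 with it in Cy3. ASP at 3 d had medians of -0.035, -0.017 and -0.023 with treated RNA in Cy5 and 0.082, 0.064 and 0.018 with it in Cy3. For ASP at 4 d they were -0.639, 0.052 and -0.059 with treated RNA in Cy5 and 0.445, 0.025 and 0.019 with it in Cy3. Scale (the log base), centring and the numerator therefore stay unstated, and the values were treated as log ratios without loess normalization.

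Groups were the drug and time given in the labels, with 3 biological replicates each, per the design text. A replicate is a dye-swap pair of a direct and a reverse array. The labels do not say which direct array goes with which reverse array, so α-MSH arrays were paired by the order of their database numbers, which fall into runs A, B and C, and ASP arrays, all of run D, by their repeat numbers. ASP at 2 d had 2 pairs and 1 lone reverse array, which was kept as a replicate after the dye correction. No 2 arrays held identical values over most of their probes. Replicates of a group correlated across probes between 0.236 and 0.353 for ASP at 3 h, -0.007 and 0.451 at 1 d, 0.101 and 0.382 at 2 d, 0.468 and 0.508 at 3 d and 0.424 and 0.479 at 4 d. They correlated between -0.103 and 0.23 for α-MSH at 1 d to 4 d and between -0.721 and 0.059 for α-MSH at 3 h.

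For the main results each array was centred on its median, the dye effect of each probe, estimated over all arrays of the drug, was removed, and the 2 arrays of a pair were averaged. The 30 replicates were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups shared their estimate of the spread. Each group mean was tested against 0, and contrasts gave the mean over the 5 times, the dependence on time (a moderated F over 5 times) and the difference between the drugs. A probe was tested where at least 2 of 3 replicates of each group involved had a value. P-values were adjusted by Benjamini-Hochberg and a probe was called at an adjusted p under 0.05. Untreated cells were the other channel of every array, so the background is a log ratio of 0. Whether the times or the drugs shared untreated RNA is not stated.

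In simulated arrays with the real missing values, medians, dye bias and probe spread, 200 probes were changed in 1 group. For α-MSH at 3 d, with 38430 probes tested, 3% of the probes changed 1.5-fold, 50.7% of those changed 2-fold and 84.8% of those changed 4-fold were recovered, and 2 of 94 calls were false. For ASP at 3 d, with 27923 probes tested, the shares were 19.4%, 73.1% and 98.5%, and 15 of 142 calls were false. With 200 changed probes, a change under 2-fold was therefore often not detectable with 3 replicates, and for ASP the false calls exceeded a share of 0.05. Where more probes change, the adjustment is less strict. Of the 3108 real calls for ASP at 3 d, 1041 changed 2-fold or more, so most were smaller.

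Alternatives fixed before the data were examined were the deposited values without centring, only probes with a value on all 59 arrays, pairs by title number, single arrays with the pair as a random block or taken as independent (both with a dye term per drug), the pair number as a fixed block, the array run as a random block, only the replicates of the groups compared, a minimum of 1.5-fold, each replicate left out, and the α-MSH values within runs A and B. Chosen after seeing the data were a loess correction (span 0.3) of each array against the dye profile of the probes, which is the mean with treated RNA in Cy3 minus the mean with treated RNA in Cy5, divided by 2, a fit without α-MSH at 3 h, the ASP mean without 3 h, and the scores. A treatment effect would cancel from the dye profile with equal numbers of arrays in both dyes and no missing values. It does not cancel fully here, because ASP at 2 d had a lone reverse array and spots without a value differed between arrays. A score is the mean log2 ratio of the called higher probes minus that of the called lower probes, divided by 2, in each replicate. Its mean was tested with an exact sign-flip test, which takes the replicates as independent. Other splits of the samples were made by turning the sign of replicates or regrouping them.

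The probe numbers were compared with the gene identifiers, symbols and synonyms of a mouse RefSeq table and 0 matched, and the files do not pair them with names. The gene lists fixed beforehand (pigment, melanosome transport, lineage regulators and others) could therefore not be tested. The rule for named genes took, per drug and time, the 3 largest rises and falls among calls with a value and one sign in all 3 replicates. Because the numbers have no gene names, at most 2 probes that rose and 2 that fell are printed, the largest of each drug under this rule. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.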

Results

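The series followed gene expression in melan-a cells, an immortal line of pigmented melanocytes from C57BL6 mice, after they were exposed to one of 2 ligands of the melanocortin receptor of pigment cells. Alpha-melanocyte stimulating hormone (α-MSH) activates this receptor and was given at 100 nM. Agouti signaling protein (ASP), the natural antagonist of the receptor, was given as recombinant mouse protein at 10 nM. Cells were treated for 3 h or for 1, 2, 3 or 4 days, and the RNA of treated cells was hybridised together with RNA of untreated cells on 2-colour arrays. Each of the 10 combinations of drug and time had 3 biological replicates, with an array of each in each dye orientation. ASP at 2 d lacked 1 array with treated RNA in Cy5, and its lone array, with treated RNA in Cy3, was taken as replicate 3. Which arrays belong to 1 replicate is not labelled, so the SDs over replicates rest on the assumed pairs. The arrays analysed here were therefore 59. The value table listed 38591 probes, and between 22218 and 38371 of them had a value on a given array. Values are log ratios, taken as log2, and likely run treated over untreated, as the design text writes the hybridisation. Before any dye correction, ASP profiles at 2 d and 3 d and at 3 d and 4 d correlated between the dye orientations at 0.202 to 0.33. α-MSH profiles at 3 d and 4 d correlated at -0.322 and -0.398. A dye bias that turns sign with the dye of the treated RNA gives such negative values. Of the 26 probes called for α-MSH at 3 d, however, 21 kept their sign at 4 d with treated RNA in Cy5 and 24 with it in Cy3. Such agreement would be the same with numerator and denominator exchanged. The numerator is not stated, so that "higher" and "lower" rest on the reading of treated over untreated. The opposition between the drugs rests on both having the same numerator, which is not stated. If the dye bias had one direction in all runs, the array medians at 3 h and 1 d argue against different numerators. There, in both drugs, every median was below 0 with treated RNA in Cy5 and above 0 with it in Cy3. For ASP at 2 d and 4 d some medians broke this pattern. The number of arrays limits the precision: the median standard error of a group mean was 0.221 on the log2 scale for α-MSH at 3 d and 0.191 for ASP at 3 d. The files do not pair the probe numbers with gene names, so genes and pathways could not be named, and probes are given by their number.

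**Figure D1:**
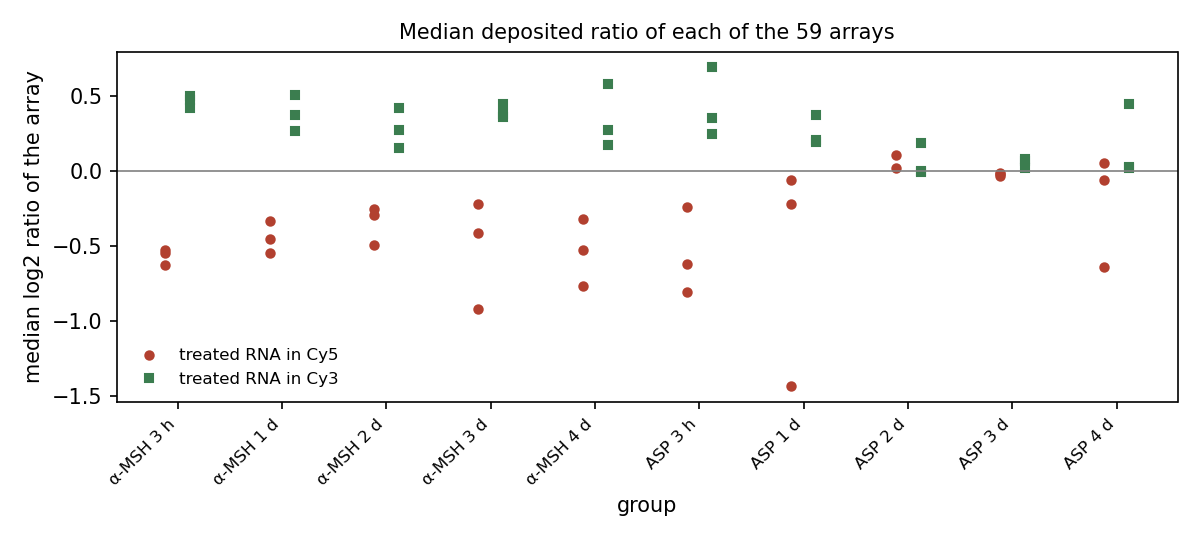
Median deposited log2 ratio (y axis) of each of the 59 arrays by group (x axis), with circles for treated RNA in Cy5 and squares for treated RNA in Cy3. The medians run from -1.435 to 0.108 with treated RNA in Cy5 and from -0.011 to 0.69 with treated RNA in Cy3, and lie closest to 0 for ASP at 2 d and 3 d.

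The first question was which transcripts α-MSH changed at each time. At 3 d, 26 of 38430 probes passed an adjusted p of 0.05 in limma, 9 of them higher and 17 lower in treated cells. Which direction had more calls depended on the processing: 114 were higher and 70 lower with single arrays and the pair as a random block, 74 and 50 with single arrays taken as independent, 48 and 44 among probes with a value on all arrays, 18 and 15 without replicate 1, and 3 and 1 without replicate 2. The changes of the 26 were large, with a median of 2.54-fold among the higher and 2.23-fold among the lower probes, and all 26 had one sign in every replicate. Among these the deepest fall was that of probe 1768586_1, which fell by 2.56 on the log2 scale (SD 0.43, n = 3, limma adjusted p = 0.0015). It did not pass without replicate 2 (adjusted p = 0.066) and stood at an adjusted p of 0.05 without replicate 3. Probe 1779209_1 rose the most, by 2.2 on the log2 scale (SD 0.4, n = 3, limma adjusted p = 0.019), although it did not pass when any of the 3 replicates was left out or without centring. At 3 h, 1 d, 2 d and 4 d limma called 0 probes. The 0 at 3 h does not show a lack of response, because replicates 1 and 2 ran opposite there. They correlated at -0.806 over 18694 probes, so that their values largely cancelled in the mean. At an unadjusted p under 0.05 there were 510 probes at 3 h, 795 at 1 d, 862 at 2 d and 1914 at 4 d, compared with 1991 at 3 d. Between 38406 and 38430 probes were tested at each time, and chance alone gives a share of 0.05. The counts at 3 h, 1 d and 2 d lay well below that share and those at 3 d and 4 d near it. They therefore show no clear excess of small p-values. The 0 at 4 d depended on the processing: single arrays taken as independent gave 122 calls at 4 d and pairing arrays by their title numbers gave 66. The 26 calls at 3 d became 4 without replicate 2 and 2 without replicate 3, and 0 when the spread was estimated from the 3 replicates of that group alone.

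Averaged over the 5 times, α-MSH changed 83 of 38366 probes, 61 higher and 22 lower. The split moved from 73.5% higher to 58.8% higher, 50 against 35 probes, when the dye bias of each array was removed by loess. The score of these probes, the mean log2 ratio of the higher probes minus that of the lower probes divided by 2, was 0.056 ± 0.319 (SD, n = 3) at 3 h, 0.273 ± 0.522 at 1 d, 0.531 ± 0.369 at 2 d, 0.965 ± 0.206 at 3 d and 0.997 ± 0.098 at 4 d. The test of dependence on time nevertheless called 0 probes in limma, with 518 at an unadjusted p under 0.05 and 10 in the fit of single arrays taken as independent. Those 518 of 38366 tested lie below the share of 0.05 that chance alone gives. The arrays of α-MSH fell into runs A, B and C by their database numbers. The mean score of the 83 probes was 0.685 in run A (5 replicates), 0.62 in run B (8 replicates) and 0.04 in run C (2 replicates, of 3 h and 1 d), but the probes were chosen on these same replicates, which raises the scores. Across probes, the mean profiles of runs A and B correlated at 0.068 only. The count was 31 without replicate 1 at 2 d, the lowest of the 15 fits that left out a replicate, and 175 without replicate 1 at 3 h, the highest. It was 0 when the spread was estimated from the 15 α-MSH replicates alone.

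**Figure D2:**
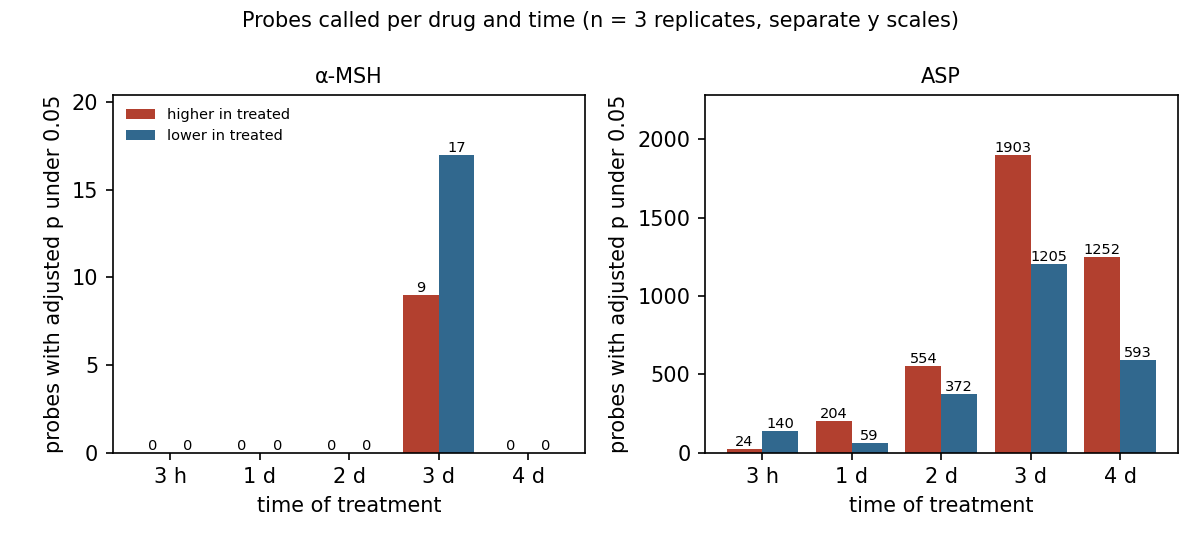
Number of probes with a limma adjusted p under 0.05 (y axis, with separate scales) at each time of treatment (x axis) for α-MSH, left, and ASP, right, with 3 replicates per group. Bars show probes higher and lower in treated cells: α-MSH has calls at 3 d only, and ASP goes from 24 higher and 140 lower probes at 3 h to 1903 higher and 1205 lower probes at 3 d.

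ASP had many more probes called than α-MSH, and most of them at 3 d and 4 d. Replicates of α-MSH at each time came from more than 1 run, those of ASP all from run D, and the doses differed. The difference in counts can therefore not be credited to the drugs alone. With ASP, 164 probes passed in limma at 3 h, 24 higher and 140 lower. At 1 d, 263 passed, 204 higher and 59 lower, a balance that turned to 133 higher and 184 lower without centring, and at 2 d, 926 passed, 554 higher and 372 lower. At 3 d, 3108 of 27923 tested probes passed, 1903 higher and 1205 lower, and 1041 of them changed by 2-fold or more. At 4 d, 1845 of 34156 passed, 1252 higher and 593 lower, with 725 changed by 2-fold or more. Changes were of similar size at 3 d and 4 d, with a median of 1.79-fold among the higher probes at 3 d and 1.84-fold at 4 d. Probe 1794161_1 rose the most, by 3.76 on the log2 scale at 3 d (SD 0.2, n = 3, limma adjusted p = 1.9e-08), after 0.7 ± 0.94 at 1 d and 2.27 ± 0.71 at 2 d. The deepest fall was that of probe 1795447_1, which fell by 3.19 on the log2 scale at 3 d (SD 0.29, n = 3, limma adjusted p = 0.00016), and stood at -2.49 ± 0.45 at 2 d and -2.89 ± 0.28 at 4 d.

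These counts depended on the replicates and on the dye bias. An increase from 3 h to 1 d was not stable: the counts at 3 h and 1 d were 602 and 347 with the dye bias removed by loess, 483 and 317 without centring, and 345 and 193 with the pair number as a block. With 1 replicate left out, the calls at 3 h were 733, 58 or 8 without replicate 1, 2 or 3. At 1 d they were 33 without replicate 1, at 2 d 386 without replicate 2 and 426 without replicate 3, at 3 d between 1539 and 1623, and at 4 d 1212, 785 or 1159 without replicate 1, 2 or 3. With the spread estimated from the 3 replicates of a group alone, 204 probes passed at 3 d and 0 at 3 h, 1 d, 2 d and 4 d, where 4267, 4760, 5106 and 6264 probes had an unadjusted p under 0.05 in the shared fit. With the dye bias removed by loess, the counts were 602, 347, 1617, 4404 and 2916 from 3 h to 4 d, and the share of higher probes at 1 d fell from 77.6% to 57.3% and at 4 d from 67.9% to 57.0%.

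The next question was whether the times under ASP shared their changes. Of the probes tested at both 3 d and 4 d, 808 were higher at both and 332 lower at both, against 76.2 and 21.4 for independent lists, and 2 were called in opposite directions. The calls at 1 d were also found later: of 221 probes called at 1 d and tested at 3 d, 191 were called at 3 d in the same direction, against 14.5 for independent lists. A set of 128 probes was called in one direction at 1 d, 2 d, 3 d and 4 d. Both results rest on the 263 calls at 1 d, which leaned on replicate 1. Without replicate 1, 2 or 3, 20, 122 or 179 of the 263 stayed called. After loess, 308 probes were called at 1 d and tested at 3 d. Of these, 259 were called at 3 d in the same direction, against 24.6 for independent lists. Whether the times shared untreated RNA is not stated, and shared RNA would raise such overlaps. The 3 h profile stood apart. Its mean log2 ratios correlated across probes between -0.027 and 0.022 with those of the later ASP times, while the later times correlated with each other between 0.257 and 0.499 (probes are not independent replicates). Of 129 probes called at 3 h and tested at all 5 times, 16 were called at a later time, against 17.4 for independent lists. The probes called at 4 d had a score of 0.009 ± 0.023 (SD, n = 3) at 3 h, 0.331 ± 0.012 at 1 d, 0.469 ± 0.087 at 2 d and 0.755 ± 0.022 at 3 d. The differences between successive times exceeded the spread between replicates. The test of dependence on time called 879 of 27278 probes for ASP, and 344 without replicate 3 at 3 h, 433 without replicate 2 at 3 h and 524 without replicate 3 at 3 d. Averaged over the times, ASP changed 5184 probes, 3388 higher and 1796 lower, which became 3348 and 3339 with the dye bias removed (65.4% against 50.1% higher) and 2789 and 3214 without centring, so that the balance between the directions is not settled.

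**Figure D3:**
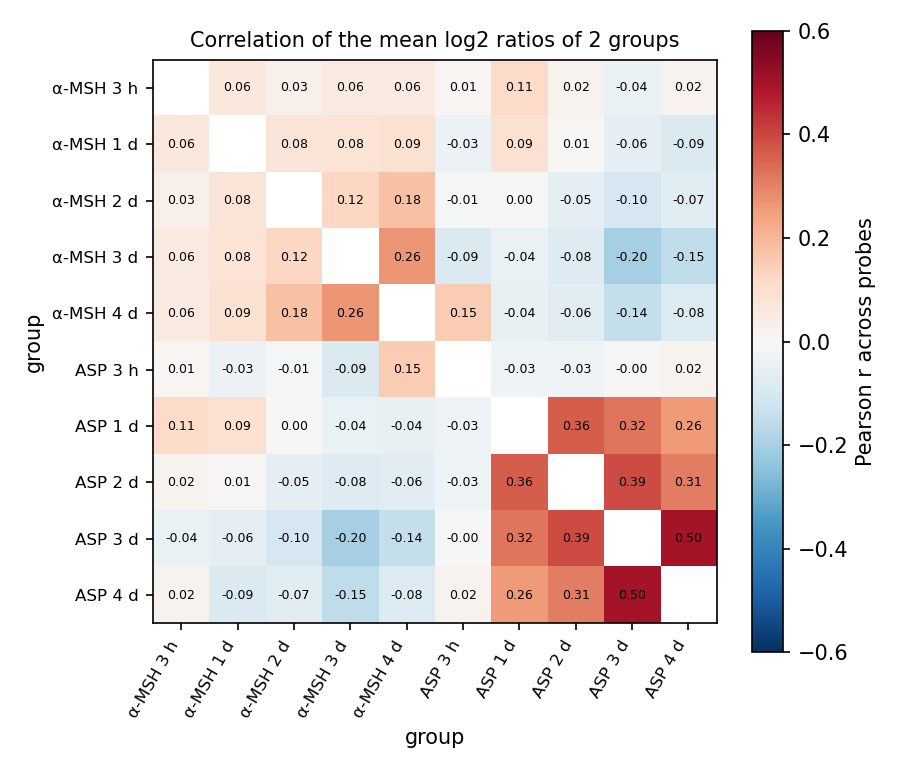
Pearson correlation across probes (colour and printed value) between the mean log2 ratios of each pair of groups, with the groups on both axes. ASP at 1 d to 4 d form a block with correlations from 0.257 to 0.499, ASP at 3 h lies outside it, and α-MSH at 3 d and ASP at 3 d correlate at -0.201.

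The last comparison set the 2 drugs against each other, since one activates and the other antagonises the same receptor. Probes changed by α-MSH went the other way under ASP. Of the 82 probes called for α-MSH over the times and also tested for ASP, 52 were called for ASP in the opposite direction, against 6.7 for independent lists, and 3 in the same direction, against 8.9. Of 60 probes higher with α-MSH, 49 had a mean log2 ratio below 0 with ASP, and of 22 lower with α-MSH, 21 were above 0. The median of the higher probes was 0.45 with α-MSH and -0.35 with ASP, and that of the lower probes -0.61 with α-MSH and 0.94 with ASP. Scored in the ASP arrays, the 83 probes stood at -0.058 ± 0.049 (SD, n = 3) at 3 h, -0.64 ± 0.05 at 1 d, -0.674 ± 0.08 at 2 d, -0.847 ± 0.049 at 3 d and -0.859 ± 0.029 at 4 d. The mean over the 15 ASP replicates was -0.616 ± 0.306 (SD), below 0 in 15 of 15, with a two-sided exact sign-flip p of 6.1e-05, the smallest that 15 replicates can give. The test takes the replicates as independent, although all were of run D and it is not stated whether they shared untreated RNA. Probe 1768586_1, which fell with α-MSH, rose with ASP by 1.87 on the log2 scale at 1 d, 1.5 at 2 d, 2.44 at 3 d and 2.65 at 4 d (SD between 0.1 and 0.5, n = 3, limma adjusted p between 1.7e-05 and 0.014).

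**Figure D4:**
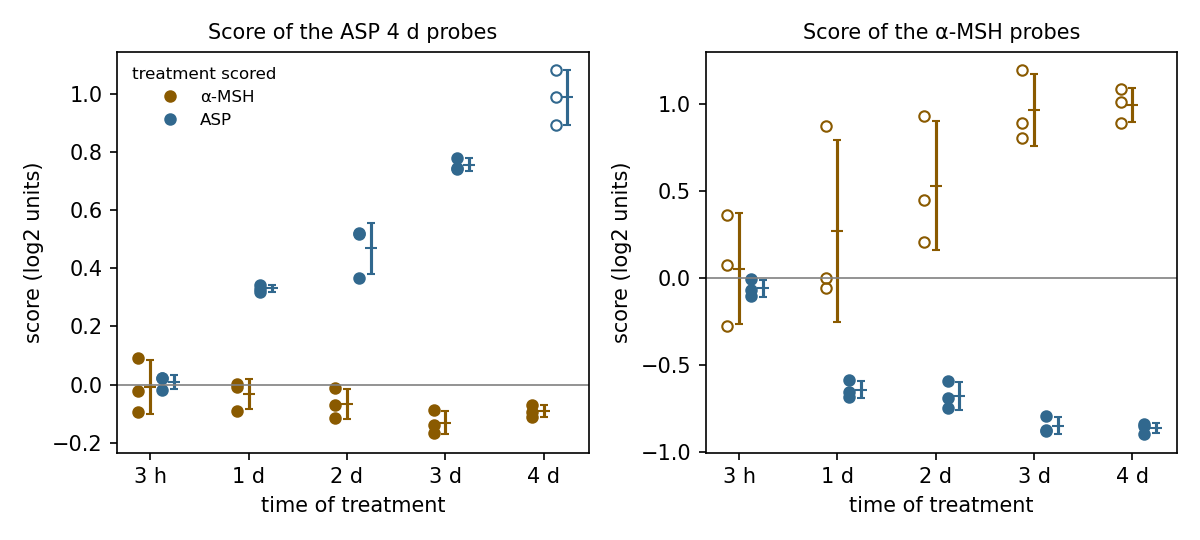
Score in log2 units (y axis) of the probes called for ASP at 4 d, left, and for α-MSH over the times, right, in each replicate by time of treatment (x axis). Points are replicates, bars are the mean and SD of 3, and open points mark the groups in which the probes were chosen: the α-MSH probes reach 0.997 with α-MSH and -0.859 with ASP at 4 d.

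In the other direction the shift was smaller. The probes called for ASP over the times had a mean score of -0.052 ± 0.072 (SD) over the 15 α-MSH replicates, below 0 in 13 of 15 (two-sided exact sign-flip p = 0.0147). By time it was -0.007 ± 0.136 (SD, n = 3) at 3 h, -0.027 ± 0.042 at 1 d, -0.042 ± 0.042 at 2 d, -0.128 ± 0.034 at 3 d and -0.057 ± 0.019 at 4 d. Within run B the mean was -0.072 over 8 replicates (exact sign-flip p = 0.00781, the smallest that 8 replicates can give), and within run A it was -0.04 over 5 replicates, where the exact test cannot go below 0.062 and gave p = 0.375. The run A replicates at 1 d to 4 d lay between -0.094 and -0.076, and that at 3 h, which ran opposite to replicate 2, at 0.13. Over 2 d to 4 d the mean was -0.076, below 0 in 9 of 9 replicates, of which 1 at 2 d rounds to 0 (exact sign-flip p = 0.00391, the smallest that 9 can give). These sign-flip tests also take the replicates as independent, although it is not stated whether they shared untreated RNA. Across probes, the mean log2 ratios of the drugs correlated at 0.013 at 3 h, 0.093 at 1 d, -0.052 at 2 d, -0.201 at 3 d, -0.083 at 4 d and -0.221 over the times. At 1 d the sign turned to -0.117 among probes with a value on all arrays, to -0.009 with the dye bias removed and to -0.076 without ASP replicate 1.

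Tested directly, the drugs differed at 3 d in 1836 of 27898 probes in limma, 751 higher and 1085 lower with α-MSH than with ASP. They differed in 860 probes at 4 d, 219 at 2 d, 7 at 1 d and 0 at 3 h, where 2222 probes had an unadjusted p under 0.05 and the fit of single arrays taken as independent called 3. Those 2222 of 38274 tested are little above the share of 0.05 that chance alone gives. Over the times, 3079 of 27253 probes differed, 1307 higher and 1772 lower with α-MSH, which turned to 2015 and 1715 without ASP replicate 1 at 1 d. All ASP arrays were of another run than the α-MSH arrays, so in these differences drug and run cannot be told apart. Leaving out a replicate gave between 975 and 1694 calls at 3 d, with 975 without α-MSH replicate 3 and 1222, 1153 or 1182 without ASP replicate 1, 2 or 3. At 4 d it gave between 424 and 690, with 477 and 424 without α-MSH replicates 1 and 2 and 426 without ASP replicate 2. The counts at 2 d were 52 and 61 without α-MSH replicates 1 and 2 and 71 and 95 without ASP replicates 2 and 3, and at 1 d they lay between 0, without α-MSH replicate 1, and 13. With only the replicates of the groups compared, the counts were 465 at 3 d, 231 at 4 d and 0 at 2 d and 1 d.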

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

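The tests that use the loess correction, the test of array quality, the tests on the lean of the ASP probes with α-MSH and the tests on the opposite replicates of α-MSH at 3 h were chosen only after the results were seen. Over 20 combinations of a group with a measure of its arrays, 5 had an array far from the others, where chance gives about 1 in 20. In Cy5 over Cy3 orientation, 1 direct array of ASP at 1 d (replicate 1) had a median of -1.435, while the other 5 lay between -0.371 and -0.06. A direct array of α-MSH at 3 d (replicate 3) had -0.921, while the others lay between -0.447 and -0.22. The number of probes with a value was 34893 on a reverse array of α-MSH at 3 h and 33184 on a reverse array of α-MSH at 1 d, both of run C, against at least 37279 and 37858 on the others of their groups. A reverse array of α-MSH at 4 d had 38058 values against at least 38261.

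Responses to the drugs differed in 7 probes at 1 d, 219 at 2 d, 1836 at 3 d and 860 at 4 d, and in 3079 over the times, and the response to ASP differed between times in 879 probes. Drug and array run cannot be told apart in the differences between drugs, because all ASP arrays form a run of their own.

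The number of ASP calls was 164 at 3 h and 3108 at 3 d, although the step from 3 h to 1 d turned with the processing (602 and 347 calls after loess). Dye bias as the whole cause is argued against by the counts after the loess correction, 602 at 3 h and 4404 at 3 d. The count at 3 d alone could not decide, because the medians of those arrays lay between -0.035 and 0.082, which left little bias to remove. The calls at 3 h went from 164 to 602 with the correction. Dye bias that hid calls at 3 h therefore stays open as a part of the cause. If array quality acts on the spread alone, better arrays at 3 d would leave the size of the change as it was. Yet the score of the probes called at 4 d was 0.746 higher at 3 d than at 3 h, against replicate SDs of 0.022 at 3 d and 0.023 at 3 h. Whether quality also changed the size of the ratios was not tested, since no channel intensities were used. Spots missing at later times as the whole cause are argued against by the probes with a value on all arrays. These had 594 calls at 3 h and 2734 at 3 d, 4.6 times as many. This rise was smaller than the main one from 164 to 3108, so missing spots as a part of the cause stay open. A response that builds up with time under ASP remains as a hypothesis, and growth of the cultures or time in culture was not tested.

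Probes called for ASP leaned the other way with α-MSH, with a mean score of -0.052 over 15 replicates. Dye bias left after averaging is argued against by the loess correction, after which the mean was -0.045 (exact sign-flip p = 0.0178), at -0.032 on the arrays with treated RNA in Cy5 and -0.059 on those with it in Cy3, although in centred values without that correction the same arrays stood at 0.006 and -0.111. An origin in 1 run alone is argued against at 1 d to 4 d, where the score was -0.083 in run A (SE 0.004, 4 of 4 below 0) and -0.062 in run B (SE 0.023), but cannot be told apart over all times, because replicate 1 at 3 h stood at 0.13 and brought run A to -0.04 (SE 0.043) against -0.072 in run B. Untreated RNA shared between the drugs, if there was any, would move the score above 0 and not below it. Opposite action of the ligands on their receptor is a hypothesis that these tests leave open. It also needs the same numerator in both drugs' ratios, which is not stated. The array medians at 3 h and 1 d argue for the same numerator, if the dye bias had one direction in all runs.

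At 3 h, α-MSH replicates 1 and 2 ran opposite, with a correlation of -0.806 over 18694 probes, and the signs held in both dyes: the direct and reverse arrays of a replicate correlated at 0.476 and 0.512 after loess. Dye bias is argued against by the 4 correlations between their arrays, the highest of which was -0.471. A difference between runs A and B at large is argued against by the other times, where such replicates correlated at -0.078 or above. An exchange of treated and untreated RNA in replicate 1 stays open: with its sign turned it correlated at 0.298 with α-MSH at 3 d, where replicate 2 stood at 0.278, and at 0.051 with replicate 3, which does not decide, since replicate 2 as labelled correlated with replicate 3 at 0.076. A difference between the cultures in some other condition was not tested.

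Turning the sign of 1 replicate in a group of 3 gives 4 patterns, too few for a share under 0.05. For α-MSH at 3 d, 1 of the 4 patterns, the real one with 26 calls, gave as many, and the highest other gave 0. In ASP the real pattern was the 1 pattern of 4 with as many calls at each time, with 164 against 3 for the highest other at 3 h, 263 against 9 at 1 d, 926 against 95 at 2 d, 3108 against 143 at 3 d and 1845 against 34 at 4 d. For α-MSH at 1 d, 2 d and 4 d, all 4 patterns gave 0. At 3 h of α-MSH all 4 gave at least the real 0, and turning replicate 1 gave 66 calls, which points to the structure of these samples described above.

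The 6 replicates of both drugs at a time have 10 splits, also too few for a share under 0.05. The real split was the 1 split of 10 with as many calls at 1 d (7 against 1 for the highest other), 2 d (219 against 1), 3 d (1836 against 2) and 4 d (860 against 1), and at 3 h all 10 splits gave 0. For results over the times, 100 splits were compared. For α-MSH over the times (83 against 24 for the highest other) and ASP over the times (5184 against 1994), only the real split gave as many calls. The same held for the difference over the times (3079 against 388) and the dependence of ASP on time (879 against 230). A share of 1 in 100 is the smallest these splits can give. Chance is then unlikely as the source of these counts, provided that the replicates were independent, which is not known. For the dependence of α-MSH on time the real count was 0 and the highest other 1; all 100 necessarily gave at least 0, so this comparison says nothing.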

How the results depend on the processing

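The loess correction, the fit without α-MSH at 3 h, the ASP mean without 3 h and all scores were chosen after seeing the data. ASP had more calls than α-MSH at 3 d in every setting that gave both counts, and the causes of the moves were not tested unless stated. Without centring, calls were 37 for α-MSH at 4 d, 483 and 1553 for ASP at 3 h and 2 d, 1383 for ASP dependence on time, and 1, 15 and 391 for the difference between the drugs at 3 h, 1 d and 2 d. With only the probes that had a value on all arrays, α-MSH had 92 calls at 3 d, 118 at 4 d, 205 over the times and 2 for dependence on time, ASP had 594 at 3 h and 647 at 1 d, the drugs differed in 1, 70 and 387 probes at 3 h, 1 d and 2 d, and the correlation between the drugs was -0.117, -0.183, -0.323 and -0.214 from 1 d to 4 d and -0.35 over the times. Pairs by title number gave 54, 66 and 147 calls for α-MSH at 3 d, 4 d and over the times, 371 and 486 for ASP at 3 h and 1 d, and 1 and 18 differences between the drugs at 3 h and 1 d. With the dye bias removed by loess, α-MSH had 48 and 39 calls at 3 d and 4 d, ASP had 602, 1617 and 2916 at 3 h, 2 d and 4 d and 1665 for dependence on time, the drugs differed in 2, 20, 426, 2972 and 1459 probes from 3 h to 4 d, and their correlation at 1 d was -0.009. Of the 3108 main calls of ASP at 3 d, 2968 were kept by the loess correction.

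Single arrays with the pair as a random block (estimated correlation -0.112) gave α-MSH 184, 170, 280 and 13 calls at 3 d, at 4 d, over the times and for dependence on time, gave ASP 568, 839 and 1839 at 3 h, at 1 d and for dependence on time, and gave 3, 115, 382 and 1398 differences at 3 h, 1 d, 2 d and 4 d. Single arrays taken as independent gave α-MSH 124, 122, 222 and 10 in the same order, ASP 510 and 532 at 1 d and 2 d, and 3 and 70 differences at 3 h and 1 d. The array run as a random block gave 18 for α-MSH at 4 d, 151 for α-MSH over the times, 339, 429 and 9096 for ASP at 3 h, 1 d and over the times, and 2, 11 and 5120 differences at 3 h, 1 d and over the times. The estimated correlation within a run was -0.03. All ASP replicates were of 1 run, so a correlation below 0 shrinks the modelled standard error of their mean over the times. The 9096 and 5120 calls are therefore no evidence of more changes. With only the replicates of the groups compared, calls were 0 for α-MSH at 3 d and over the times and for ASP at 3 h, 1 d, 2 d and 4 d, 204 for ASP at 3 d, 164 for ASP dependence on time, and 0, 0, 465 and 231 for the differences at 1 d, 2 d, 3 d and 4 d; fewer replicates then estimate the spread. A minimum of 1.5-fold left 31, 675 and 1028 calls for α-MSH, ASP and their difference over the times. Without α-MSH at 3 h, the spread estimated from the other groups gave 48 and 22 calls for α-MSH at 3 d and 4 d and 24 for ASP at 3 h. The ASP mean of 1 d to 4 d stayed within 1.5 times of the mean over all times.

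With the pair number as a replicate block, ASP at 3 h had 345 calls, and the block moved no other count by over 1.5 times: α-MSH had 19 calls at 3 d and 60 over the times, and ASP 2837 at 3 d and 1708 at 4 d. The numbers did not pair the samples: same-numbered replicates of different times had mean correlations of their deviations between -0.028 and 0.053, and 13 of 30 correlated best with a replicate of their own number.

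Leaving out 1 replicate gave these ranges. Calls for α-MSH ranged from 0 to 1 at 3 h and 2 d, stayed at 0 at 1 d and 4 d, and ranged from 2 (without replicate 3) to 33 at 3 d, from 31 (without replicate 1 at 2 d) to 175 (without replicate 1 at 3 h) over the times and from 0 to 1 for dependence on time. For ASP they ranged from 8 (without replicate 3) to 733 (without replicate 1) at 3 h, from 33 (without replicate 1) to 343 at 1 d, from 386 (without replicate 2) to 831 at 2 d, from 1539 (without replicate 3) to 1623 (without replicate 1) at 3 d, from 785 (without replicate 2) to 1212 (without replicate 1) at 4 d, from 4567 to 5215 over the times and from 344 (without replicate 3 at 3 h) to 1127 for dependence on time. For the difference between the drugs they ranged from 0 to 21 (without ASP replicate 1) at 3 h, from 0 (without α-MSH replicate 1) to 13 (without ASP replicate 3) at 1 d, from 52 (without α-MSH replicate 1) to 241 at 2 d, from 975 (without α-MSH replicate 3) to 1694 at 3 d, from 424 (without α-MSH replicate 2) to 690 at 4 d and from 2654 to 3730 over the times. The correlation between the drugs ranged from -0.029 to 0.062 at 3 h, from -0.076 to 0.118 at 1 d, where only leaving out ASP replicate 1 turned the sign, from -0.088 to -0.027 at 2 d, from -0.23 to -0.163 at 3 d, from -0.122 to -0.055 at 4 d and from -0.27 to -0.154 over the times.

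The score of the α-MSH probes under ASP lay between -0.789 and -0.554 with any 1 replicate left out, and that of the ASP probes under α-MSH between -0.066 and -0.043; within run A the latter was -0.04, where an exact test of 5 replicates cannot pass 0.05. Gene lists were not run, since the probes have no names. Signal over background is unknown, so which weak probes lack calls for want of signal was not determined.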

Other observations

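The tests here that use the loess correction were chosen only after the results were seen, as was the look at which probes stayed called, whereas the test on the number of ASP calls at 3 h with a replicate left out was written down before its result. A hypothesis was that the calls of ASP at 3 h rest on 1 replicate. The prediction was that the number of calls would fall below 10% of the 164 without 1 replicate and not without the others, and the numbers were 8 without replicate 3, 58 without replicate 2 and 733 without replicate 1. By probe, however, 3 of the 164 stayed called without replicate 3, 16 without replicate 2 and 147 without replicate 1, so the loss is not particular to replicate 3 and the hypothesis stays open. Dye bias as their whole source is argued against by the 602 calls at 3 h after the loess correction.

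Most calls of ASP at 3 h were lower in treated cells, 140 of 164, whereas at 1 d to 4 d between 59.8% and 77.6% were higher. This contrast depended on the setting: 32 calls at 3 h were higher and 26 lower without replicate 2, 133 calls at 1 d were higher and 184 lower without centring, and after loess 18.9% were higher at 3 h and between 53.8% and 57.3% at the later times. Of 135 of the probes called at 3 h and also tested at 1 d, 32 had the same sign there, and of 132 tested at 4 d, 59 had. The mean log2 ratios of ASP at 3 h correlated across probes at 0.15 with α-MSH at 4 d, the highest of its correlations with the other 9 groups.

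Scored with the 83 probes called for α-MSH over the times, the α-MSH replicates at 1 d lay between -0.057 and 0.875, and the ASP replicates at 1 d between -0.683 and -0.585.

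After loess, the deviations of the direct and reverse array of a pair from the mean of their group in the same dye orientation correlated at 0.393 on average for α-MSH at 3 h and 0.377 at 4 d with pairs by database number, against -0.179 and -0.234 with pairs by title number. At 3 d both pairings are the same and gave 0.404. In the other 7 groups, where the pairings are also the same, the averages lay between -0.201 and 0.156.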
